A study of Mus musculus with 6 samples.

How the data were processed

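The series measured GATA-1 occupancy by chromatin immunoprecipitation and sequencing (ChIP-seq) in ES-EP cells, a line of erythroid progenitors derived from mouse embryonic stem cells. There were 6 libraries. Per the labels, 2 came from proliferating cells, 3 from cells differentiated for 24 h, and 1 was input DNA of differentiating cells. The differentiating libraries are numbered 1A, 1B and 2. Nothing in the labels says whether the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

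The deposited files list aligned reads, 1 line per read, with chromosome, start, end, read sequence, a match code and strand. The coordinates are on mm9, per the submitters' processing notes. The aligner, its settings and the read filters are not given in the sources used here. The lists hold no peaks and no values per gene. The files differ between the conditions. Reads were 27 bases long in the proliferating libraries and the input and 34 in the differentiating libraries. The proliferating files carried no match codes and held 33989 and 21838 reads outside the 21 chromosomes used, against 0 in the other files. Read length and file format therefore cannot be told apart from the condition.

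One read was kept per position and strand. Distinct positions numbered 5341196 and 3909586 for proliferating replicates 1 and 2, 10489604 for differentiating replicate 2 and 8399188 for the input. Duplicates were 18.8% of the reads of library 1A and 20.4% of those of library 1B, and at most 2.83% elsewhere. Libraries 1A and 1B shared 985788 positions, 33.8% of the smaller, while no other pair shared more than 0.813%. They were merged into differentiating replicate 1, with 5379462 distinct positions, and counted as 1 replicate.

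Reads were shifted by 51 bp, from a common fragment length of 102 bp estimated by strand cross-correlation. Pairs of reads on opposite strands at the estimated distance were 10.0 times the background in differentiating replicate 1. In the other replicates they were 1.55 to 2.29 times. Whether this excess adds to the regions called in differentiating replicate 1 was not tested. Windows of 200 bp in steps of 50 bp were tested with a Poisson model against the larger of the genome mean and the scaled input in 1, 5 and 10 kb. Windows with a Benjamini-Hochberg q under 0.01 at least 4 reads and at least 4 times the expected count were merged within 200 bp. Windows whose input was over 10 times its mean in 1 kb were left out. The input of differentiating cells served as the control for both conditions. Occupied regions were those called in at least 2 of the 4 replicates, whichever the condition. When the input was called against the pooled immunoprecipitated reads, 58 regions passed.

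Reads per region were compared with limma voom, scaled by trimmed means of M values (TMM) over the regions, with Benjamini-Hochberg adjustment and a threshold of 0.05, two-sided. A count test of another kind was planned first and was kept for counts as deposited. The deposited files list reads, and the counts per region were made here, so the planned substitute limma voom was used. Scaling over the regions removes a difference in pull-down efficiency that is uniform over regions, and no other, so a change is relative to the typical region. Values in RPM below are reads scaled by library size and this factor.

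Base sequences were taken from the reads, as the majority base of all libraries at each position, since no genome was used here. Of the read bases, 99.0% matched the majority. The window of 201 bp around the summit was read in full in the median region, and 6122 regions had at least 80% of it read. At 2 kb from the summit a median of 47.1% of bases was read, so that comparison used only the positions read in both windows, a departure from the plan. The GATA site WGATAR was fixed before the data were examined. The other 16 motifs, the 80% rule and the classes built on them were chosen after the files and the differential calls had been seen.

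Regions named below follow a rule fixed before the data were examined. It takes the 10 with the smallest adjusted p among those higher and among those lower whose conditions do not overlap, and the 10 with the highest mean occupancy. Genes were not assigned, because a gene annotation of mm9 was not used here. For the same reason the gene lists fixed beforehand, the promoter share and the list part of the naming rule were not run. Coordinates are 1-based and carry an uncertainty of 1 base, since the files do not state how starts are counted.

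The region caller was tested on simulated reads at the depth of proliferating replicate 1. It recovered 58.8% of 500 implanted regions with 10 added reads and 99.6% with 20, and 0.994% of the calls were false in the latter. Background and input were drawn from a Poisson model, which the caller also assumes. The false share of this simulation therefore does not carry over to the regions called in the real libraries. The differential test was tested on 6260 simulated regions in 5 runs with 200 changed regions. It recovered 6.4% of the changes of 2-fold and 45.6% of those of 4-fold, and 2.99% of the calls were false. These counts had an assumed dispersion of 0.05 and no technical difference between conditions. The false share therefore does not carry over to the regions called here. A floor of 3 reads amounts to 0.403 and 0.974 RPM in proliferating replicates 1 and 2 and to 0.470 and 0.373 RPM in differentiating replicates 1 and 2. Intervals of shares are 95% Wilson intervals, and they and the floor cover counting error only. Alternatives covered scaling, filters, depth, duplicates, region thresholds, the handling of 1A and 1B, and each replicate left out. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.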

Results

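GATA-1, a zinc finger transcription factor required for red cell development, was mapped in ES-EP cells under 2 growth conditions. Proliferating cells were kept with erythropoietin at 2 u/ml, stem cell factor at 100 ng/ml, IGF-1 at 40 ng/ml and the glucocorticoid dexamethasone. Differentiating cells received erythropoietin at 10 u/ml, insulin and the glucocorticoid receptor antagonist mifepristone for 24 h. Each condition had 2 replicates, and 1 input library of differentiating cells gave the background. After removal of duplicates the replicates held between 3909586 and 10489604 reads.

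GATA-1 occupied 6260 regions in at least 2 of the 4 replicates, with a median width of 400 bp. Of these, 1676 were called in all 4 replicates. Proliferating replicates 1 and 2 gave 8800 and 2851 regions, and differentiating replicates 1 and 2 gave 9959 and 5971. Of the regions of proliferating replicate 2, 94.9% were also called in proliferating replicate 1, and 30.6% of those of replicate 1 in replicate 2. Of the regions of differentiating replicate 2, 65.5% were also called in differentiating replicate 1, and 39.3% of those of replicate 1 in replicate 2. A further 9669 regions were called in 1 replicate alone, 5140 of them in differentiating replicate 1 and 3303 in proliferating replicate 1. Relative to the reads of the input, regions were most frequent on chromosomes 19 and 11, at 1.58 and 1.37 times the expected number, and least frequent on chromosomes 14 and 1, at 0.697 and 0.759 times.

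The 6260 regions held 2.57% of the reads of proliferating replicate 1 (95% interval 2.55 to 2.58) and 1.49% of those of replicate 2 (1.48 to 1.51). In differentiating replicates 1 and 2 they held 2.24% (2.22 to 2.25) and 1.39% (1.38 to 1.40), against 0.299% in the input. The means were 2.03% ± 0.758 (SD, n = 2) in proliferating and 1.81% ± 0.598 (SD, n = 2) in differentiating cells. This difference was smaller than the spread between replicates (exact permutation test, two-sided, p = 0.667, where the smallest possible p is 0.333).

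**Figure D1:**
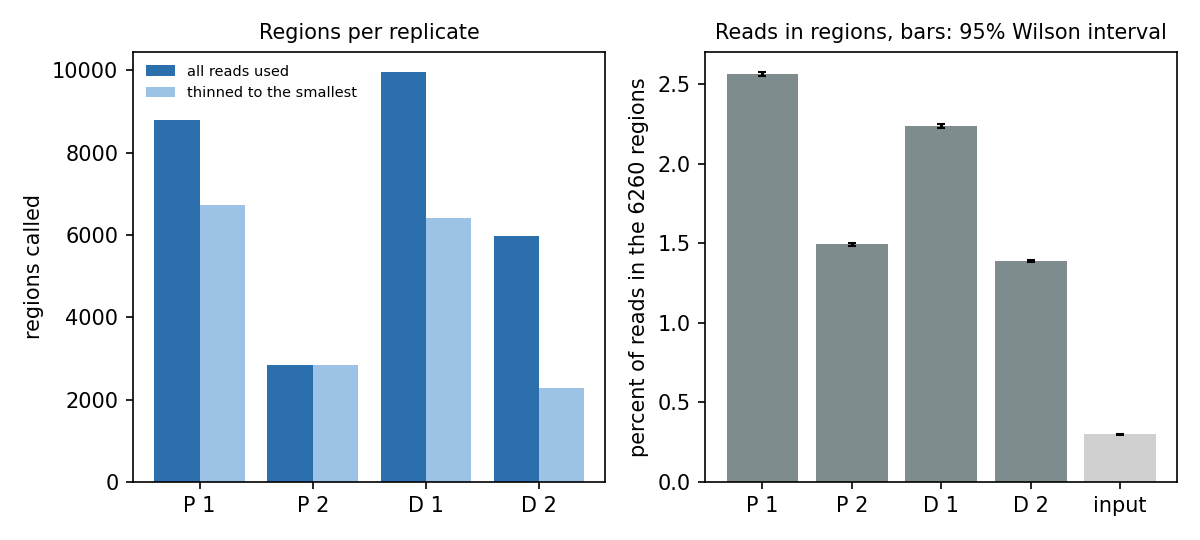
Left, regions called in proliferating (P) and differentiating (D) replicates 1 and 2, with all distinct reads and after thinning to the depth of the smallest. Right, percent of reads in the 6260 regions with 95% Wilson intervals, from 1.39% to 2.57% in the replicates and 0.299% in the input.

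The GATA recognition site marked nearly all occupied regions. WGATAR lay within 100 bp of the summit in 94.3% of the 6122 well read regions. This share has no counterpart 2 kb away, where windows were only partly read. Over positions read in both windows, 54.8% of summit windows held the site, against 15.9% of windows 2 kb away (odds ratio 6.39). These 12520 window pairs use each region 2 times and are not independent. Site density was 14.8 per kb within 20 bp of the summit and 2.00 per kb at 2 kb, and the median distance of the nearest site was 17.5 bp. The composite of a partial E-box and a GATA site, known from complexes of GATA-1 with TAL1, was 12.7 times as frequent at summits as 2 kb away, at 11.7% against 0.919% of windows. The CACC box of KLF factors and the STAT5 site were 2.29 and 2.22 times as frequent at summits (Fisher's exact test, adjusted over 17 motifs, p = 2.44e-36 and 4.40e-16). Motifs of other factors were also more frequent there, among them CTCF (2.71 times, adjusted p = 0.00154), PU.1 (2.04 times, 7.36e-07) and AP-1 (1.72 times, 8.61e-10). The excess was thus not particular to KLF and STAT5. The octamer, included as a comparison motif, was found in 0.296% of summit windows and 0.407% of the others (adjusted p = 0.175). ETS and NF-Y motifs were not more frequent at summits either.

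**Figure D2:**
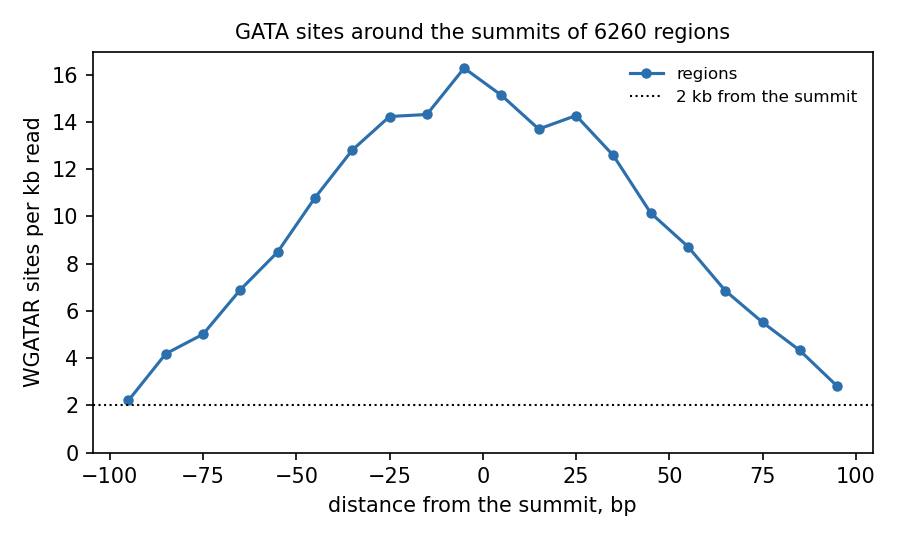
Density of WGATAR sites per kb read (vertical axis) by distance from the summit in bp (horizontal axis) over 6260 regions in bins of 10 bp. The density peaks at 16.3 per kb next to the summit, and the dotted line marks the 2.00 per kb found 2 kb away.

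The question of the design was how GATA-1 occupancy differs between proliferating and differentiating progenitors. Occupancy was lower in differentiating cells at 397 regions and higher at 126, of 6260 tested (limma voom, adjusted p under 0.05). The lower regions changed by a median of -1.74 on the log2 scale and the higher ones by 1.60. Median occupancy of the lower regions was 5.27 RPM in proliferating and 1.48 in differentiating cells, and that of the higher regions 1.82 and 5.63. Without adjustment 1658 regions had p under 0.05. The conditions did not overlap at 56.0% of all regions, where chance gives 33.3%. These counts rest on the scaling and on single libraries. Scaling on background bins left 1 higher and 24 lower regions, and scaling on total reads left 1 and 69. Without proliferating replicate 1 there were 0 higher and 28 lower regions, and without replicate 2 there were 6 and 65. Leaving out differentiating replicate 1 gave 453 and 573, and leaving out replicate 2 gave 858 and 820.

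**Figure D3:**
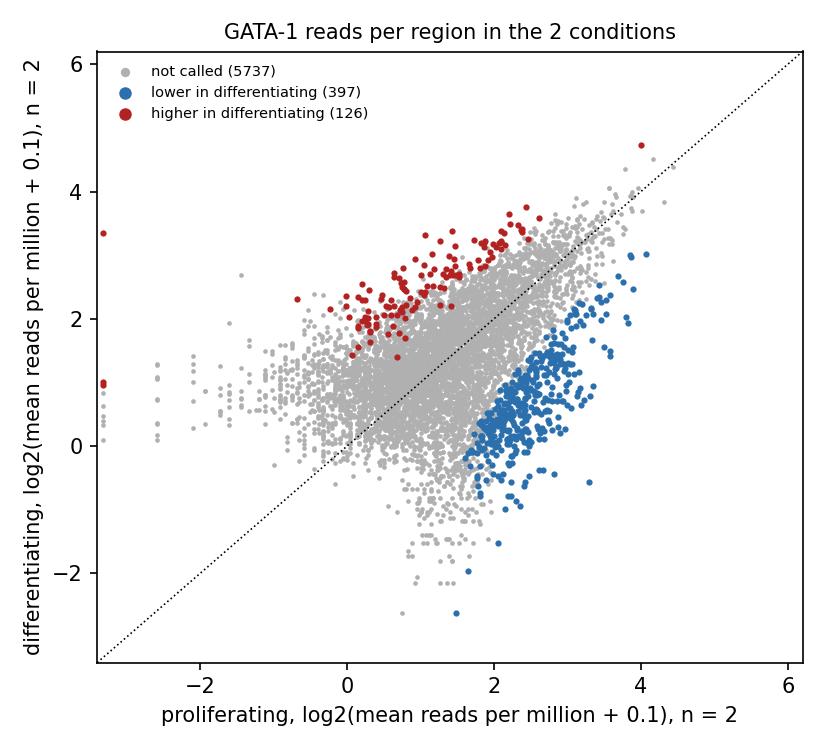
Mean RPM per region in proliferating (horizontal axis) and differentiating cells (vertical axis), both as log2 of the mean of 2 replicates plus 0.1. Each point is 1 of 6260 regions, with the 397 lower in blue and the 126 higher in red on either side of the dotted line of equality.

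Among the regions lower in differentiating cells, that on chromosome 3 from 117455251 to 117455800 fell from 9.27 ± 0.20 to 1.56 ± 0.452 RPM (SD, n = 2 each). Its log2 change was -2.58 (SE 0.39, limma adjusted p = 0.000322), and an AGATAA site lay at 117455523 to 117455528 in the sequence CAGGCTGAGAAGAGATAAGATGCTCTGGAT. The region on chromosome 16 from 95709251 to 95710050 fell from 9.80 ± 0.375 to 1.62 ± 0.519 (log2 change -2.53, adjusted p = 0.000322) and held 4 GATA sites around its summit. On chromosome 18, the region from 11954201 to 11955400 fell from 11.8 ± 1.17 to 2.56 ± 0.954 (log2 change -2.16, adjusted p = 0.000322). On chromosome 8, the regions starting at 53132201 and 80163301 changed by -2.74 and -2.47, and those at 122104651 and 69591851 by -2.39 and -1.81. The others were on chromosome 19 at 52405851 (-2.56), chromosome 9 at 48603201 (-2.31) and chromosome 1 at 33598501 (-2.25). Their adjusted p was 0.000418. All 10 had at least 2 GATA sites within 100 bp of the summit, as did 89.3% of all well read lower, 61.7% of uncalled and 56% of higher regions. Under scaling on background bins 8 of the 10 were called, and without proliferating replicate 1 there were 9.

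Among the regions higher in differentiating cells, that on chromosome 19 from 9107901 to 9108550 rose from 1.81 ± 0.657 to 7.61 ± 0.127 RPM (SD, n = 2 each). Its log2 change was 2.28 (SE 0.43, limma adjusted p = 0.00141), and a TGATAG site lay at 9108350 to 9108355. The region on chromosome 1 from 93270101 to 93270600 rose from 2.13 ± 1.12 to 7.96 ± 1.60 (log2 change 2.21, adjusted p = 0.00153). On chromosome 16, the region from 17638301 to 17638750 rose from 1.97 ± 0.887 to 7.10 ± 0.505 (log2 change 2.13, adjusted p = 0.00218). The region on chromosome 3 from 51033951 to 51034500 was the most occupied of the 10, and rose from 4.53 ± 0.434 to 12.4 ± 0.854 (log2 change 1.39, adjusted p = 0.00296). Regions on chromosome 6 at 66999301 and chromosome 5 at 73583051 rose by 2.30 each on the log2 scale. The remaining ones were on chromosome 7 at 148318001 (2.07) and 142913051 (1.96), chromosome 15 at 76082651 (1.79) and chromosome 10 at 75159651 (1.74). None of the 10 was called under scaling on background bins or total reads, or without proliferating replicate 1, and 4 were not called without replicate 2. With background bins the log2 change at chromosome 19 was 1.91 and that at 148318001 on chromosome 7 was 2.05. The changes on chromosomes 6, 5 and 16 fell to 1.68, 1.83 and 1.73, and all 10 were smaller than with TMM. Without proliferating replicate 1 the changes at chromosome 19 and at 148318001 on chromosome 7 were 1.66 and 2.76. Those on chromosomes 6 and 5 fell from 2.30 each to 0.74 and 1.28, that on chromosome 1 from 2.21 to 1.35 and that on chromosome 16 from 2.13 to 1.38.

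Of the 10 most occupied regions, 9 were not called as changed between the conditions. Of these 9, 1 was called with 1A and 1B as separate samples. Some of them were also called when differentiating replicate 1 or 2 was left out, which leaves a single library in that condition. The highest mean was on chromosome 16 from 32509101 to 32510100, with 21.5 ± 3.50 RPM in proliferating and 20.9 ± 5.28 in differentiating cells (log2 change -0.018, limma adjusted p = 0.968). A TGATAA site lay at 32509853 to 32509858 in the sequence CAGTCAGGGAGCTGATAAGGAGGCTGCAGA. Of the 10 strongest regions, 1 was called, on chromosome 8 from 83023801 to 83025650, with 15.9 ± 1.82 and 26.4 ± 1.46 (log2 change 0.69, adjusted p = 0.0243). It was not called with background bins (log2 change 0.59) or total reads (0.60), without proliferating replicate 1 (0.84) or 2 (0.62), or among regions called in all 4 replicates (0.78). On chromosome 1 from 36976451 to 36977600 the values were 17.8 ± 3.73 and 22.7 ± 4.10 (adjusted p = 0.182). Of these 10 regions, 4 were on chromosome 8 beyond 70 Mb, a part that also held 1.52 times the autosomal median of input reads per Mb.

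Regions lower in differentiating cells held more GATA sites per region than the higher and the uncalled ones. WGATAR was found in 388 lower, 112 higher (89.6% of 125) and 5275 uncalled regions (94.1% of 5605), and was missing from 4 lower ones (higher against lower, Fisher's exact test adjusted over 17 motifs, p = 4.72e-05). The mean number of sites was 2.76 ± 1.08 (SD) in lower, 1.72 ± 1.04 in higher and 1.83 ± 0.970 in uncalled regions. Paired GATA sites within 20 bp were present in 43.9% of lower, 10.4% of higher and 18.9% of uncalled regions. Fisher's exact test gave adjusted p = 8.48e-12 for higher against lower and 6.12e-26 for lower against uncalled regions. The glucocorticoid response element was present in 14 lower regions (3.57%), 0 of 125 higher regions and 43 of 5605 uncalled regions (lower against uncalled, adjusted p = 5.05e-05; higher against lower, adjusted p = 0.0659). KLF sites were rarer in lower regions, at 5.10%, than in uncalled (12.9%, adjusted p = 8.51e-06) or higher ones (17.6%, adjusted p = 0.000222), and higher and uncalled regions were not told apart (adjusted p = 0.291). STAT5 sites were more frequent in higher regions, at 14.4%, than in lower (4.08%, adjusted p = 0.000954) or uncalled ones (6.08%, adjusted p = 0.0168). SP1 sites were also rarer in lower than in uncalled regions (1.79% and 6.74%, adjusted p = 5.19e-05), and MYB sites more frequent (8.42% and 4.91%, adjusted p = 0.012). The KLF pattern also takes in a form that holds an SP1 site on the other strand, so the KLF and SP1 results are not independent. Median GC content was 45.3% in lower, 48.2% in uncalled and 49.3% in higher regions. It was not modelled for the contrasts with uncalled regions. Without proliferating replicate 1 no regions were called higher, and without replicate 2 few were. In the latter case higher and lower regions did not differ at p under 0.05 in paired GATA (Fisher's exact test, p = 0.397), KLF (0.0536) and STAT5 sites (0.236). All of both held WGATAR. Paired GATA was then in 16.7% of higher and 40% of lower regions, and KLF in 33.3% and 4.62%. Lower regions were fewer too without proliferating replicate 1 or 2. Against uncalled regions they did not reach p under 0.05 for WGATAR (Fisher's exact test, p = 0.401 and 0.0515) and KLF (0.243 and 0.0574). The same held for the glucocorticoid element without replicate 2 (0.122). The shares still differed, with WGATAR in 100% of lower and 94.3% of uncalled regions in both cases. KLF was in 3.70% and 4.62% of lower and 12.5% of uncalled regions. Paired GATA was in 48.1% and 40% of lower and in 20.2% and 20.1% of uncalled regions. All but the WGATAR comparison were chosen after the calls had been seen, and regions are not independent replicates. Patterns with the same letters in another order were also compared between higher and lower regions. As large a difference was given by 10 of 100 for paired GATA, 7 of 55 for KLF and 15 of 100 for STAT5. For the glucocorticoid element it was 1 of 100.

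**Figure D4:**
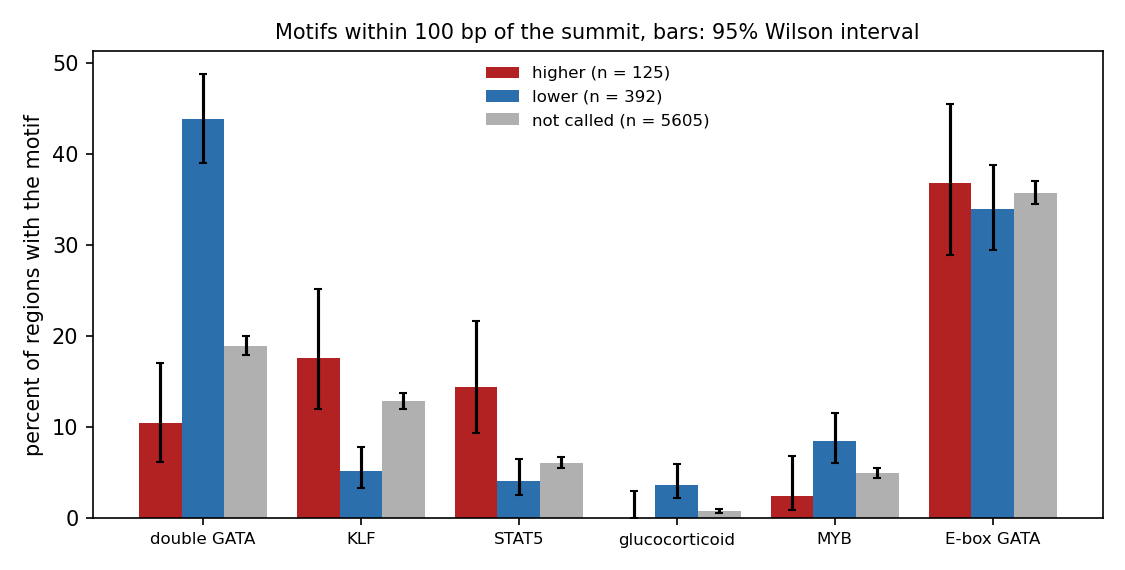
Percent of regions with each motif within 100 bp of the summit (vertical axis) among well read regions, 125 of them higher and 5605 uncalled, with 95% Wilson intervals. Paired GATA sites reach 43.9% in lower and 10.4% in higher regions, and the composite E-box GATA site differs little, at 33.9% and 36.8%.

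Calls in both replicates of a condition divided the regions in another way. In both differentiating but not both proliferating replicates 2245 regions were called, 717 of them in neither proliferating replicate. In both proliferating but not both differentiating replicates there were 1021, with 554 in neither differentiating replicate, and 1676 were called in all 4. The order turned when all replicates were thinned to the smallest, to 703, 1482 and 1093 regions in the 3 groups. The numbers of regions per condition were thus not comparable at these unequal depths.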

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

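The tests of GC content across whole chromosomes, and both tests of the part of chromosome 8 beyond 70 Mb, were chosen after the result had been seen.

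The input, which entered the comparisons only as background, showed an excess of reads on part of chromosome 8. Beyond 70 Mb the median 1 Mb bin held 1.52 times the autosomal median of input reads, and the part before it 0.954 times. Over the chromosome as a whole 66.4% of bins lay above the autosomal median, and a GC effect stayed open because chromosome 11, of similar GC, reached 1.18. For the part beyond 70 Mb, the ratio to bins of the same GC on other autosomes was 1.40, and the lowest ratio over the 6 libraries, of both read lengths, was 1.52, which argues against GC content and against 1 read length as the whole cause. A gain of that segment in the ES-EP line is a candidate explanation that was not tested by another method, and the boundary at 70 Mb was read from the same data.

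At the regions higher in differentiating cells the input also stood above its surroundings, with 2.27 times the flank density within 200 bp of the summit, against 1.77 times at lower regions. The mean was 5.56 ± 3.55 reads (SD) at 126 higher and 3.68 ± 2.46 at 397 lower regions. Uncalled regions matched on GC, and others matched on GC and mean occupancy over the 4 replicates, held fewer reads than the higher regions (permutation p = 1e-05 for both, the smallest that 100000 resamples can give). This argues against GC bias and mean occupancy as the whole cause. Strength in differentiating cells, the source of the input, stays open, since the match did not use it. Higher regions had a median of 5.63 RPM there and 1.82 in proliferating cells. Copy number or mappability remains open as part of the cause, since the flanks of higher regions also held 1.17 times the reads of those of lower regions. Copy number would raise summit and flanks alike. The summit stood 2.27 times over its flanks at higher and 1.77 times at lower regions, which argues against copy number as the whole cause. Chromatin that is more open in differentiating cells may add to the input excess, but there was no proliferating input to compare.

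Reads outside the 21 chromosomes numbered 33989 in proliferating replicate 1 and 21838 in proliferating replicate 2, and there were 0 in the other libraries.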

How the results depend on the processing

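All alternatives were planned except limma trend and the motif shares under other calls, which were chosen after seeing the data. The count of 523 differential regions was 25 with scaling on background bins, 70 on total reads, 844 with 1A and 1B as separate samples and 61 among regions called in all 4 replicates. Leaving out 1 replicate gave between 28 and 1678, where the lone sample of a condition is assumed to vary like the other condition. Median-of-ratios factors gave 518, a minimum of 20 reads 517, thinning 622, stricter regions 368, and limma trend 767. The 126 higher regions became 245 with thinning, 201 with limma trend, 79 in stricter regions, 286 with 1A and 1B separate, 272 with the block and 12 among regions called in all 4 replicates. The fit with the replicate number as a block called 888, but replicates of the same number did not deviate together (correlation 0.007 across regions). Of the 3 splits of the 4 replicates into pairs, the real one gave 523 regions and the highest other 0, and 3 splits cannot give a share under 0.05. The cause of these changes was not tested.

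With a stricter threshold, proliferating replicate 2 gave 1730 regions, differentiating replicates 1 and 2 gave 4860 and 3176, and 4037 regions were occupied, with 1410 in both differentiating but not both proliferating replicates and 961 in all 4. Thinning gave 6409 and 2273 regions in the differentiating replicates, with 703 and 1093 in the same groups. Occupied regions numbered 1676 when all 4 replicates were required, and 4414 to 5681 without 1 replicate. With duplicates kept, differentiating replicate 1 gave 98584 regions, so its duplicates decide that count. The strong region on chromosome 8 from 125243551 to 125244700 turned from -0.071 to 0.47 on the log2 scale without differentiating replicate 2 and to -0.56 without replicate 1. The share of lower regions with paired GATA sites lay between 40% and 50% under the settings run. Besides the cases without 1 replicate given in the report, fewer regions were left among those called in all 4 replicates. There, higher and lower regions did not differ at p under 0.05 in paired sites (16.7% and 42.9%, Fisher's exact p = 0.111). They did not differ in the GATA site (12 of 12 and 49 of 49) or STAT5 (0 of 12 and 0 of 49). With background bins or total reads 1 higher region was left. Lower against uncalled, Fisher's exact p was 0.644 with background bins, 0.183 with total reads and 0.629 in all 4 for the GATA site, 0.064 with background bins and 0.134 with total reads for KLF, and 0.0622 in all 4 for the glucocorticoid element. For paired sites, lower against uncalled, Fisher's exact p was 0.00113 with background bins, 6.22e-07 with total reads and 0.00145 in all 4. The shares of uncalled regions with paired sites were then 20.2%, 20.1% and 22%. Higher against uncalled was not run under other settings. The GATA odds ratio was 8.39 within 50 bp and 7.04 in stricter regions. Alternatives on gene lists, promoters and a further count model were not run.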

Other observations

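Of the tests below, that of whole chromosome segments was chosen after the result had been seen, as were the ratios by chromosome.

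Higher and lower regions differed in paired GATA, KLF and STAT5 sites, and the glucocorticoid element was in 0 higher and 14 lower regions (Fisher's exact test, adjusted p = 0.0659). Without proliferating replicate 1 no regions were called higher. Without replicate 2 few were, and the differences did not reach p under 0.05 (Fisher's exact p = 0.397, 0.0536 and 0.236 for paired GATA, KLF and STAT5 sites). For this contrast, and not for those with uncalled regions, base composition as the whole cause is argued against, since all 4 motifs kept p under 0.05 with GC content in a logistic model, but the KLF odds fell from 3.97 to 2.47, and the glucocorticoid value rests on 0 higher regions; whole segments are argued against by 5 Mb bins that differed by 0.029 on the log2 scale. Some patterns with the same letters in another order differed as much between higher and lower regions, so chance matches stay open. Only 1 of 4 motifs, the glucocorticoid element, exceeded 95% of its reordered patterns, while 10 of 100 did as well as paired GATA sites, 7 of 55 as well as KLF and 15 of 100 as well as STAT5. Efficiency of single libraries stays open, since regions with paired sites differed by 0.317 on the log2 scale between differentiating replicates (lower in replicate 1) and -0.051 between proliferating ones, against -0.84, -0.38, -0.83 and -0.43 in the 4 pairs across conditions. Read length or alignment stays open too, since flank reads moved with the calls by 0.53. The flank medians were 0.20 at higher and -0.33 at lower regions, smaller than the medians of the regions themselves (1.60 and -1.74). An effect of differentiation or of the change of medium stays open as well and was not tested.

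The ratio of differentiating to proliferating reads per chromosome fell in alphabetical order of the chromosome names, from 0.11 on chromosome 1 to -0.077 on chromosome X on the log2 scale. Over 20 chromosomes, which are not replicates, Spearman's rho was -0.964 and Pearson's r -0.935 (permutation p = 0.0001 each, the smallest that 10000 resamples can give, adjusted p = 0.00025 over 5 ratios). The ratio of input to proliferating reads gave rho = -0.779 (permutation p = 0.0001, adjusted p = 0.00025), and that of proliferating replicate 1 to 2 gave rho = 0.104 (permutation p = 0.667). Differentiating replicate 1 to 2 gave rho = -0.161 (permutation p = 0.5). The ratio of differentiating to input reads, of 34 and 27 bases, gave rho = 0.278 (permutation p = 0.231). A fall in this order was thus seen only in ratios to the proliferating reads. The proliferating files are those without match codes.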
